A study of Mus musculus with 4 samples.

How the data were processed

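Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in MC38/gp100 cells, a mouse colon adenocarcinoma line carrying the melanocyte antigen gp100. The 4 libraries fall into 2 groups of 2. One group received the solvent DMSO and the other 1 µM GSK3368712, an inhibitor of type I protein arginine methyltransferases, and both were harvested after 5 days. Per the labels' protocols, 100000 cells were taken from each group, nuclei were tagmented with a Nextera kit, libraries were amplified over 10 PCR cycles, and paired reads of 42 nt were sequenced. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

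Per the submitters' processing notes, the tools were HISAT2 2.1.0, Picard 1.113, MACS2 2.1.1.20160309, DiffBind 2.8.0 and DESeq2, and the genome build was mm10. Their settings, the handling of the transposase offset and the DESeq2 version are not given in the sources used here. The authors deposited 1 table of 97699 peaks that compares the groups. Its levels are log2 mean normalised read counts per group and over both groups, as deposited, and its fold is the log2 difference DMSO minus inhibitor, which was turned here to inhibitor minus DMSO. The deposited p-value and the adjusted p-value are the authors' own, per the file header. A further pair of columns gives, as deposited, the number of libraries of each group in which the peak was called. Values per library were not used here, so the table gives no spread within a group, and the read depth of each library is unknown.

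The planned analysis named 3 routes by the kind of values found, and the last of them applied: the authors' adjusted p-value at 0.05, with no new test across libraries. A peak counts as tested when its deposited adjusted p-value is under 1. This held for 74791 peaks, all at a log2 mean level of at least 5.16, which is 35.8 normalised reads. The Benjamini-Hochberg adjustment recomputed over these peaks was within 2% of the deposited value for 74791 of them. A standard error was derived per peak from the fold and its two-sided p-value under a normal distribution. Its median fell from 0.41 log2 in the lowest of 10 level bins to 0.08 in the highest, and the smallest fold called was 1.17 and 0.16 log2 in those bins. Stronger peaks were therefore measured with less error.

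Peaks were assigned to genes with a RefSeq gene table of GRCm38.p6, the assembly behind mm10. That table gives gene ends without strand or exons, so promoters and exons were not separated. A peak whose centre lies within 1 kb of either end of a protein-coding gene is called a gene-edge peak. Other peaks are gene-body peaks where the centre lies inside a gene, and otherwise intergenic peaks, assigned to the nearest gene end. Assignment to a gene says nothing of which gene a peak regulates. The location of called peaks was compared with tested peaks that were not called by Fisher's exact test, two-sided, and peaks are not independent replicates.

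The 31 gene lists were fixed before the data were examined, and 0 of their 852 symbols went unmatched. Each list's median fold over gene-edge peaks, 1 per gene, was placed among 10000 random lists matched on level, as a description. The same was done for the median over all of a list's peaks, which were matched on level but not on distance to a gene end and were drawn singly, so those percentiles are more extreme than whole genes would give. The number of member genes with a called peak was also set against 10000 random lists matched on tested peaks per gene, two-sided, with Benjamini-Hochberg adjustment over 62 tests. This count test was chosen after seeing the data. Its random lists were not matched on distance to a gene end, with which the share of lower peaks varied. On simulated data for the lists' comparison over 16069 genes, 1% of unchanged lists of 30 genes had a p under 0.05. Of lists with 2.5 times the chance of a lower peak, 96% did. The simulated genes were drawn at random and called independently, whereas lower peaks of the table lay near one another. These rates therefore do not show how the test behaves for lists of neighbouring genes.

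Other scalings were approximated by taking a constant off every fold and recomputing p from the derived standard error. For the scaling called library totals the constant was -0.08. It is the log2 ratio of the groups' summed normalised reads over all peaks, and no sequencing depth entered it. Simulated data over 74791 peaks had an offset of -0.3 and 200 changed peaks, as many up as down. Centring left 126 calls, of which 5 were false. It recovered 93.9% of peaks changed by 1 log2 at or above the median level and 27.7% below it. Calls in the table lie mostly in 1 direction and can move the median themselves, so the simulation does not show how centring performs there. Thresholds, level filters, merging of neighbouring peaks and windows about gene ends were also varied. Named peaks follow a rule fixed beforehand. It takes the 12 largest folds per direction among called peaks at or above the median level of tested peaks, 1 per gene and without predicted genes. It adds up to 4 members with the smallest p per list spoken of, with both directions shown where both exist. Prmt1, Prmt6, Carm1, B2m, Cd274, Nlrc5 and Pmel are always named, and so are the 3 genes with the most called peaks per direction, ties included. Some results that this rule and the lists would give are not reported here. Sequence motifs were planned but not analysed here, since no genome sequence was used. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.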

Results

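Open chromatin was compared between MC38/gp100 cells kept for 5 days in DMSO and cells kept in 1 µM GSK3368712, with 2 libraries in each group. GSK3368712 blocks type I protein arginine methyltransferases, the enzymes that place asymmetric dimethyl marks on arginines of histones and RNA-binding proteins. The table held 97699 peaks on 21 chromosomes, with a median width of 496 bp, on mm10. Normalised reads over all peaks summed to 25913087 in DMSO and 24524730 under the inhibitor, by the authors' deposited group means. Levels, folds and adjusted p-values of single peaks below come from the authors' deposited table, which carries no spread per group.

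On the authors' scale, accessibility was lower at many more sites than it was higher. By the authors' deposited table, 4558 of 74791 tested peaks were lower under the inhibitor and 368 were higher. The lower peaks had a median log2 fold change of -0.68, a ratio of 0.624, and the higher peaks one of 0.68, a ratio of 1.6. Among peaks at or above the median level, the deepest loss lay 233 kb from Plk2, which encodes a polo-like kinase, and the largest gains lay near the collagen gene Col5a1 and inside Ahnak. At least 1 log2 unit separated the groups at 981 lower and 78 higher peaks. In all, 4926 peaks changed, 6.59% of those tested, and 92.5% of them were lower. With folds scaled to library totals, here the groups' sums of normalised reads over peaks and not sequencing depth, 2698 peaks were lower and 617 higher. Of these changed peaks, 81.4% were lower. The labels name no spike-in that would set an absolute scale, and taking -0.17 off every log2 fold would give as many higher as lower peaks. At an unadjusted p under 0.05, 11716 peaks of the table were lower and 1930 higher.

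**Figure D1:**
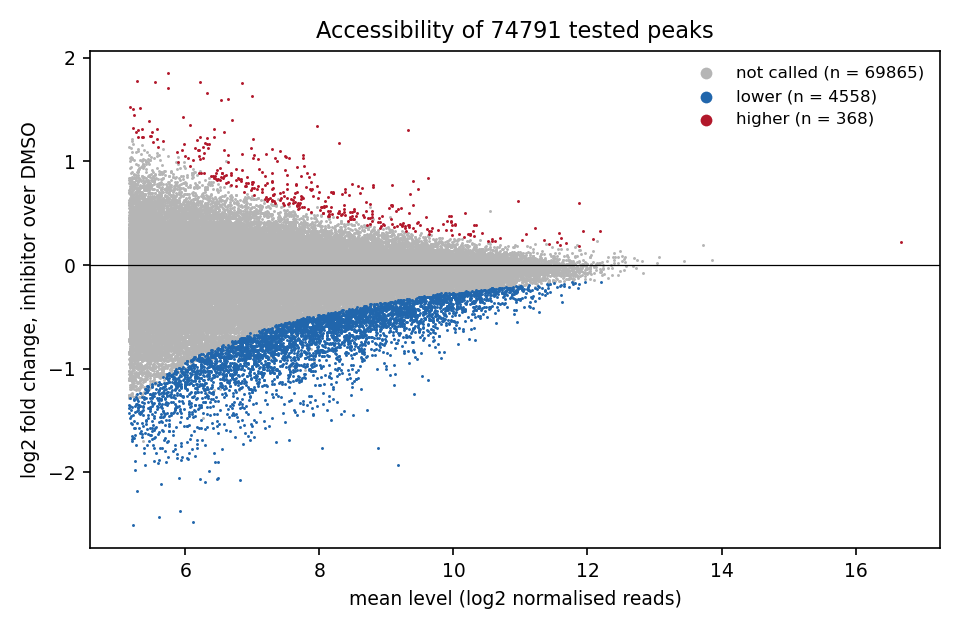
Each point is 1 tested peak, with its mean level in log2 normalised reads on the horizontal axis and its log2 fold change, inhibitor over DMSO, on the vertical axis. The 4558 lower peaks in blue outnumber the 368 higher peaks in red, and weaker peaks needed larger folds to be called.

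Among strong peaks, the largest losses lay mostly away from gene ends. The peak near Plk2, on chromosome 13 from 110632750 to 110634266, went from 917 to 241 normalised reads in the authors' deposited table, a log2 fold change of -1.93 with an adjusted p of 5.16e-52. A peak 44.6 kb from Arntl, the clock activator also known as Bmal1, had -1.76 with an adjusted p of 1.7e-33 in the authors' deposited table. It lies on chromosome 7 from 113133599 to 113134240. An intergenic peak 92.5 kb from the cytokine gene Il6, on chromosome 5 from 29920077 to 29921144, fell from 252 to 77.2 normalised reads by the authors' deposited table. The other intergenic peaks of this group, assigned to Polm, Apip, Creb5, Ubash3b and Fmod, lay 7.03, 29.3, 7.64, 329 and 45.7 kb from a gene end. Their log2 fold changes were -1.76, -1.69, -1.55, -1.51 and -1.51 in the authors' deposited table. Peaks inside Nup210l, Banp, Synrg and Mkx had -1.57, -1.49, -1.48 and -1.45 there. Mkx encodes a homeobox factor of tendon cells and Fmod a small matrix proteoglycan.

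The largest gains among strong peaks had log2 fold changes from 1.34 down to 1.03 in the authors' deposited table. An intergenic peak 39.1 kb from Col5a1, on chromosome 2 from 27846812 to 27847669, rose from 141 to 357 normalised reads in the authors' deposited table, a log2 fold change of 1.34 with an adjusted p of 2.33e-10. A broad peak of 5390 bp inside Ahnak, on chromosome 19 from 9004640 to 9010029, rose from 370 to 904 normalised reads by the authors' deposited table, with an adjusted p of 7.36e-24. A peak inside Jup, which encodes the junction protein plakoglobin, had 1.18 in the authors' deposited table. Peaks assigned to Capzb, Tmem119, Pkdcc, Arap1, Vwa5b1, Cd200r2, Cep70, Irgm2 and Sorcs2 had log2 fold changes from 1.12 down to 1.03 there.

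Some genes gathered many lower peaks. 1600014C23Rik and Serp2 each had 10 lower peaks among 30 tested, with 1 and 0 higher peaks beside them, and Rbms1 and Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, each had 9, among 29 and 25 tested. The lower peaks assigned to Serp2 spread over 207 kb of chromosome 14, from 76555202 to 76762207, with folds from -1.02 to -0.36 in the authors' deposited table. The most higher peaks per gene was 3, at Col5a1, Fmnl2, H2bc15, Nrp1 and Smg6. Of these, Col5a1, Nrp1 and Smg6 also had 2 lower peaks each. A peak inside Smg6, below the median level, rose by 1.60 in the authors' deposited table.

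**Figure D2:**
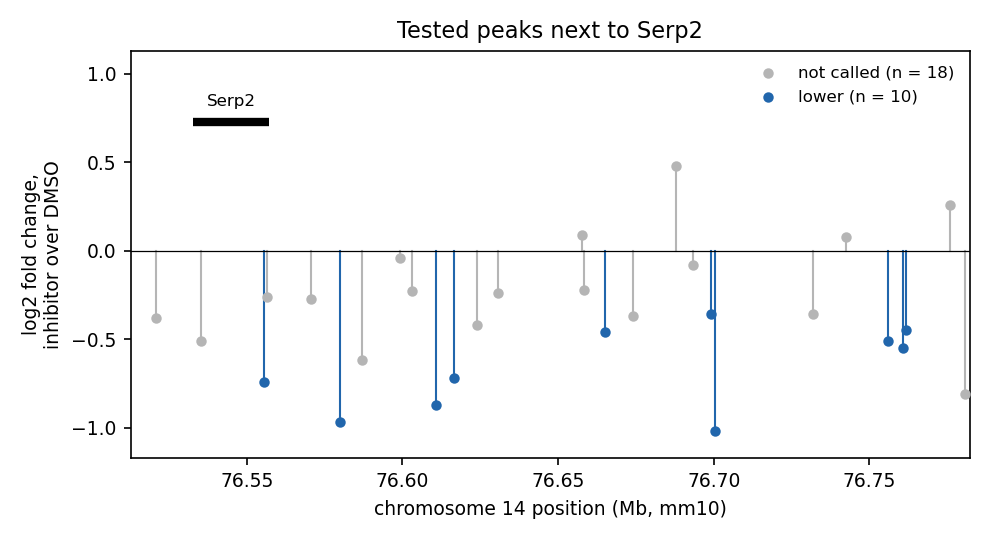
Each stem is 1 tested peak near Serp2, at its position on chromosome 14 in Mb, with its log2 fold change, inhibitor over DMSO, as its height, and the black bar is the gene. Of 28 tested peaks shown, 10 were called lower, 0 were called higher and 24 had a fold below 0.

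Losses spared the ends of genes. Of 12692 gene-edge peaks, 196 were lower, or 1.54%, against 2224 of 33181 gene-body peaks, or 6.7%, and 2138 of 28918 intergenic peaks, or 7.39%. The share was 4.97% between 1 and 5 kb from a gene end and 9.36% of peaks over 100 kb from any gene end. Gains were also scarcer at gene edges, at 0.252%, against 0.446% in gene bodies and 0.65% in intergenic DNA. The odds of lying at a gene edge were lower for lower peaks than for peaks not called, with an odds ratio of 0.207 and p = 4.35e-162, and also for higher peaks, with an odds ratio of 0.439 and p = 1.01e-06 (Fisher's exact test, two-sided). The test takes peaks as independent, which they are not, so these p-values do not measure spread between libraries. Gene edges cover both ends of a gene, since strand was not used here.

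**Figure D3:**
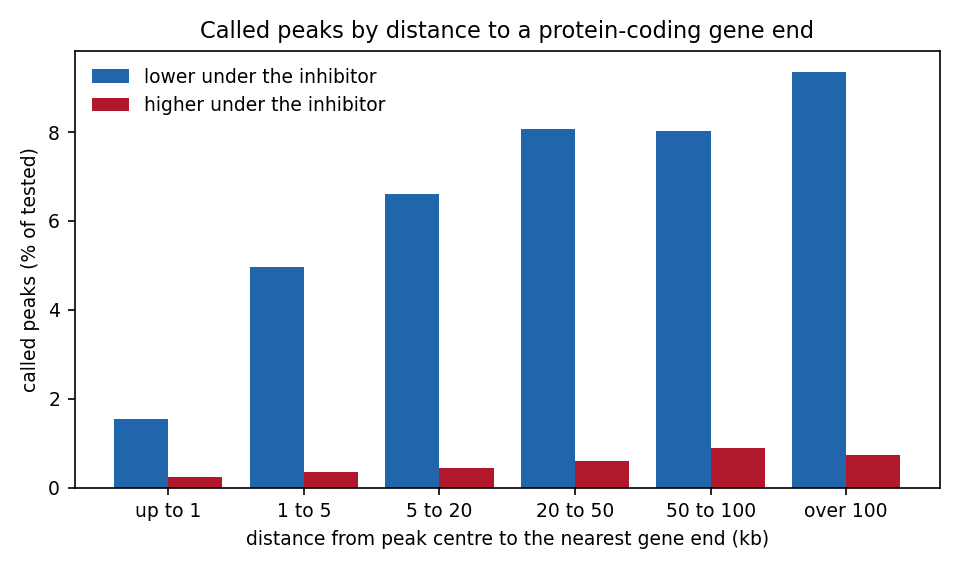
Bars give the percent of tested peaks called lower (blue) or higher (red) under the inhibitor, by distance in kb from the peak centre to the nearest end of a protein-coding gene. The lower share goes from 1.54% within 1 kb to 9.36% beyond 100 kb.

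The genes of the enzyme family itself showed little change at their own ends. In the authors' deposited table, gene-edge peaks of Prmt1, the main type I enzyme, Prmt6 and Carm1 had log2 fold changes of -0.07, 0.03 and -0.05, with adjusted p-values of 0.679, 0.939 and 0.786. Of 12 family members and partners with a tested peak, 2 had a lower peak, against 2.81 in matched random lists, and 0 had a higher one. These were Btg1 at -0.73 and Prmt3 at -0.69 in the authors' deposited table. A gene-edge peak of Btg2 at 0.65 there had an adjusted p of 0.0502, which became 0.0282 with folds scaled to library totals, and one of Prmt9 at 0.26 did not pass either. Adjusted over the list alone, 2 genes had a lower and 1 a higher peak.

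More chemokine and cytokine genes had a lower peak than matched lists did, a call that several other settings ended. Of 31 genes with a tested peak, 15 had a lower peak, against 7.52 in random lists matched on peaks per gene (adjusted p = 0.0372), and 0 had a higher one. Lower peaks lay near Il6, near Csf2, a growth factor of myeloid cells, at -2.07, near Ccl2, a monocyte attractant, at -0.84, and near Lif at -0.39, in the authors' deposited table. Adjusted over the list alone, 16 genes had a lower peak. The list's median gene-edge fold was -0.16 against -0.03 in matched lists, at percentile 0.01 of them, and its median over all 188 peaks was -0.18 against -0.07, at percentile 0. The count test was chosen after seeing the data, and with folds scaled to library totals it gave 11 genes against 5.11 (adjusted p = 0.186), after median centring 12 against 5.34 (0.0558), at FDR 0.01 10 against 5 (0.347) and at gene edges 3 against 0.4 (0.546). It gave 15 against 8.43 with level matching (0.105) and 13 against 6.73 within 50 kb (0.112), while 1 gene per 100 kb kept the call, with 13 of 23 against 6.75 (0.0372).

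Genes for RNA-binding proteins and splicing factors, which include known substrates of these enzymes, had fewer lower peaks than matched lists by the same count. Of 33 genes with a tested peak, 0 had a lower peak, against 6.79 in matched lists (adjusted p = 0.0248), and 0 had a higher one, and the same numbers held adjusted over the list alone. The smallest p-values in the authors' deposited table belonged to peaks of Rbm25, G3bp1, Khdrbs1 and Ncl, at -1.28, -0.67, -0.49 and -0.70, none of which passed. The list's median gene-edge fold was -0.03, as in matched lists, at percentile 59.9 of them, while its median over all 161 peaks was -0.03 against -0.07, at percentile 97.6. None of the other settings run on the lists adds a lower call, so a count of 0 was fixed in each and shows no stability. The adjusted p was 0.306 with folds scaled to library totals, 0.285 after median centring, 1 at gene edges, 0.347 at FDR 0.01 and 0.0744 within 50 kb. The call was kept with level matching, at 0.0496, and with 1 gene per 100 kb, at 0.0372.

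No count of lower peaks passed for the 5 lists of immune recognition and signalling genes that follow, although each lay above its matched mean. Gene-edge peaks of B2m, the light chain of class I molecules, and Cd274, which encodes PD-L1, had -0.02 and 0.00 in the authors' deposited table. A peak inside Cd274, on chromosome 19 from 29384904 to 29385317, had -1.03 there, from 67.2 to 32.9 normalised reads, and did not pass at an adjusted p of 0.0625. The gene-edge peak of Nlrc5, the activator of class I genes, had -0.15 in the authors' deposited table, with an adjusted p of 0.56. Pmel, the gene for gp100, had no peak assigned to it, and 2 peaks overlapping it belonged to neighbours. Of 18 class I antigen presentation genes 3 had a lower peak, against 2.36 in matched lists. They were Tap2 at -1.51, H2-D1 at -0.51 and Nlrc5, inside the gene, at -0.63 in the authors' deposited table, while a gene-edge peak of H2-K1 had 0.16 and did not pass. The Tap2 peak was weak, going from 89.9 to 31.3 normalised reads there. The Nlrc5 call was lost with folds scaled to library totals, at an adjusted p of 0.0958. The class I list's median over all 61 peaks was 0.01 against -0.07, at percentile 99.5 of matched sets. Its median gene-edge fold was -0.02 against -0.03, at percentile 67.8. Of 39 interferon-stimulated genes 6 had a lower peak, against 5.24, among them Trim25 at -0.51, Oasl1 at -0.50, Irf1 at -1.20 and Ifih1 at -1.05 in the authors' deposited table. Their median gene-edge fold was -0.07 against -0.02 in matched lists, at percentile 1.7 of them, while their median over all 137 peaks was -0.06 against -0.07, at percentile 68. Of 22 genes of nucleic acid sensing and interferon signalling 4 had a lower peak, against 3.92, and 1 had a higher one. Lower peaks lay near the receptor gene Ifnar2, at -0.84 with an adjusted p of 1.25e-15, in Mavs at -0.80 and near Tlr2 at -0.54 in the authors' deposited table. The higher peak, near Ifngr1, had 0.62 with an adjusted p of 0.0459 in the authors' deposited table, and 0.0577 without a level filter. Of 22 checkpoint and T cell ligand genes 7 had a lower peak, against 4.13, among them Cd86 at -1.19 and Nt5e at -1.88 in the authors' deposited table. The Nt5e peak was also weak, going from 76.1 to 20.8 normalised reads there. Of 31 death receptor, TNF and NF-kB genes 9 had a lower peak, against 7.33, with Tnfaip3 at -0.78, while a peak in Tnfrsf1b rose by 0.71 in the authors' deposited table. This list's median over all 178 peaks was -0.15 against -0.07, at percentile 0.02, while its median gene-edge fold was -0.05 against -0.03, at percentile 15.1. The adjusted p of each of these counts was 1. Adjusted over the list alone, 3, 6, 7, 9 and 9 genes in this order had a lower peak.

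Genes of matrix and mesenchyme had both gains and losses. Of 40 genes, 15 had a lower peak, against 17.1, and 7 had a higher one, against 2.41, with adjusted p-values of 1 and 0.281. The adjusted p of the higher count was 0.0248 with folds scaled to library totals and 0.0124 after median centring, so that it passed under both. The list's median gene-edge fold was 0.04 against -0.03, at percentile 99.5 of matched lists, while its median over all 421 peaks lay the other way, at -0.10 against -0.07 and percentile 4.33. A peak 39.1 kb from Col5a1 had 1.34, while peaks assigned to Thbs1, Thbs2 and Zeb2 had -2.37, -1.09 and -0.62 in the authors' deposited table. The latter lay 128 kb, 29.4 kb and 1325959 bp from a gene end. The Thbs1 peak was weak, going from 102 to 19.7 normalised reads there. Adjusted over the list alone, 17 genes had a lower and 9 a higher peak. Of 28 AP-1 and immediate early genes, 13 had a lower peak, against 9.82, among them Egr1 at -1.30, Dusp4 at -0.64 and Klf6 at -0.40, while a gene-edge peak of Jun rose by 0.73 with an adjusted p of 2.34e-09 in the authors' deposited table. Of 37 epithelial and intestinal genes 11 had a lower peak, against 8.1, with Klf5 at -1.26, Sox9 at -0.61 and Cdh1 at -0.92, while a peak near Gata4 had 0.65, in the authors' deposited table. The adjusted p of the lower count was 1 for both lists. Adjusted over the list alone, 16 and 11 genes of these lists had a lower peak.

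No count of lower peaks passed for the lists for growth, stress and metabolism. The genes with a lower peak numbered 14 of 36 for growth factor receptors and RAS-MAPK against 12 and 11 of 28 for the unfolded protein response against 7.64. They numbered 9 of 24 for hypoxia and glycolysis against 7.55, 9 of 26 for cholesterol and lipid synthesis against 5.79, and 8 of 30 for p53 targets and apoptosis against 7.68. Cell cycle genes gave 6 of 34 against 6.92, DNA repair genes 2 of 21 against 2.78, and histone modifiers 12 of 42 against 10.5. Wnt targets gave 8 of 27 against 11.1, TGF-beta genes 11 of 27 against 12.3, Hippo targets 10 of 20 against 7.92 and nuclear receptors 9 of 31 against 10.4. Clock genes gave 5 of 17 against 5.18, NRF2 targets 6 of 19 against 4.59 and housekeeping genes 6 of 19 against 3.28. Markers of other cell types gave 0 of 12 against 2.13 for blood cells and 5 of 13 against 4.88 for fibroblasts and endothelium. Melanocyte genes gave 1 of 7, where matched lists held 0 to 3, and neuronal genes 4 of 14 against 2.98. The adjusted p of each of these counts was 1. Adjusted over the list alone, the counts in the same order were 16, 13, 9, 9, 9, 6, 2, 12, 8, 11, 11, 9, 7, 7, 6, 0, 5, 2 and 4.

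Median folds outside the central 95% of matched lists went in both directions, and gene edges and all peaks often differed. At gene edges, beside the chemokine, interferon-stimulated and matrix lists, they were those of hypoxia, unfolded protein and cell cycle genes, at -0.09, -0.08 and -0.08 against -0.03 and percentiles 0.695, 1.05 and 1.7. Over all peaks the cell cycle list had -0.08 against -0.07, at percentile 30.2, while the hypoxia and unfolded protein lists had -0.14 and -0.15 against -0.07, at percentiles 0.06 and 0.015. Other low medians over all peaks were -0.16 for epithelial genes, -0.14 for TGF-beta, RAS-MAPK and clock genes and -0.10 for AP-1 genes, at percentiles 0.035, 0.05, 0.06, 0.275 and 1.48. At gene edges these 5 lists lay at percentiles 76.1, 90.7, 20.5, 34.9 and 43.6. High medians over all peaks were those of the class I and RNA-binding lists and of the neuronal list, at 0.02 against -0.09 and percentile 99.7, which had 0.12 at gene edges, at percentile 96.3.

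**Figure D4:**
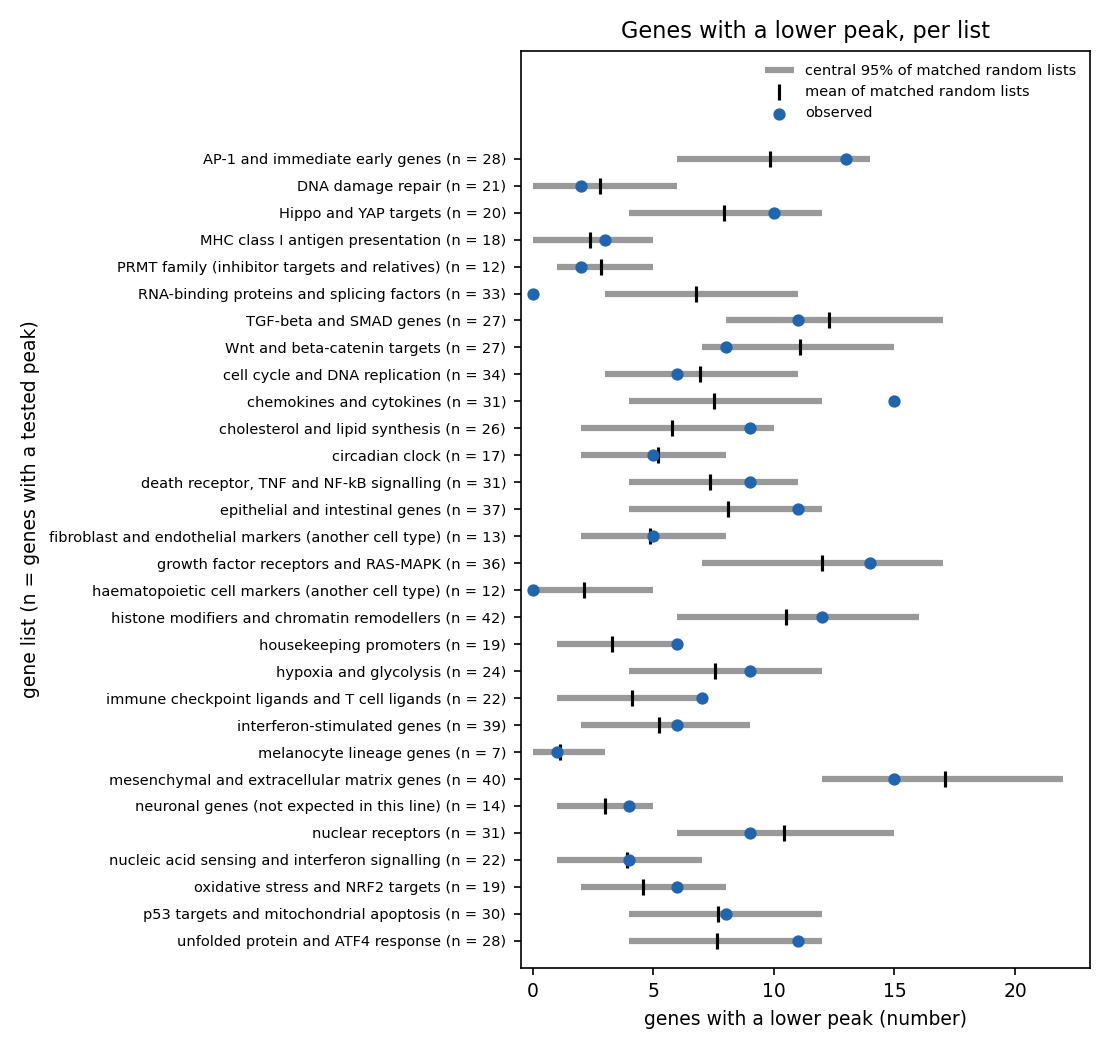
For each gene list reported, with the number of genes that had a tested peak in brackets, the blue point is the number of genes with a lower peak, the black tick the mean of 10000 matched random lists and the grey bar their central 95%. The point of the chemokine and cytokine list, at 15, lies above its bar and that of the RNA-binding list, at 0, below.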

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

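Centring on the median of tested peaks, housekeeping scaling of the count, the list count test with all its settings, and all histone counts were chosen after seeing the data. The count of changed peaks was 2781 at FDR 0.01 and 1059 with at least 1 log2 unit, since both ask for more. With library totals, meaning the groups' sums of normalised reads over peaks, it was 3315. It was 3748 with housekeeping scaling, 3424 after median centring, 6602 at FDR 0.10, 4662 without a level filter, 4649 above the median level and 4813 as merged regions. The percent lower was 93.8 at FDR 0.01, 91.5 at FDR 0.10, 81.4 with library totals, 86.6 with housekeeping scaling and 83.2 after median centring. Lists passing numbered 1 with library totals, after median centring or with level matching as well, and 0 with gene-edge peaks only, FDR 0.01 or peaks within 50 kb. After the first pair, the list that passed was the matrix list, for higher peaks. The adjusted p of the chemokine list was 0.186 with library totals, 0.546 at gene edges, 0.347 at FDR 0.01, 0.105 with level matching, 0.112 within 50 kb and 0.0558 after median centring. That of the RNA-binding list was 0.306, 1, 0.347, 0.0496, 0.0744 and 0.285 in the same order. For higher peaks of the matrix list, where the reported count had an adjusted p of 0.281, it was 0.0248 with library totals and 0.0124 after median centring, with 12 of 40 genes in both, and from 0.293 to 0.843 with FDR 0.01, level matching, 50 kb or 1 gene per 100 kb. At gene edges it was 1 with 0 genes against 0.0944, below the matched mean. Higher peaks at histone genes numbered 26 with library totals or median centring, 24 with housekeeping scaling and 8 at FDR 0.01. The cause of the moves with scaling and of the list changes was not tested. The location of lower and of higher peaks kept its direction and its call under 2 kb, 500 bp, FDR 0.01 and level matching, with odds ratios of 0.133 to 0.277 and 0.286 to 0.442. Of 167 named peaks, 157 kept their side of the threshold with library totals and 165 without a level filter. No paired analysis was possible because the table holds group values and no column per library. For the same reason refits with edgeR, DESeq2 or limma, other pseudocounts, omission of single libraries and camera or fry were not run, and motifs were not run without sequence. The read depth of each library is unknown. The derived standard error was largest for the weakest tested peaks, at 0.41 log2 against 0.08 for the strongest, and 22908 peaks were not tested.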

Other observations

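Histone genes stood out among the gains, and this group was picked after its values were seen. Of 117 tested peaks assigned to histone genes, 14 were higher under the inhibitor and 0 lower, at 11 of 62 genes. The higher peaks numbered 26 with library totals or median centring, 24 with housekeeping scaling and 8 at FDR 0.01. In the authors' deposited table the gene-edge peak of H2bc15, on chromosome 13 from 21753311 to 21754988, went from 3444 to 4330 normalised reads, with an adjusted p of 1.37e-07. Gene-edge peaks of H1f3, H2ac12, H2bc8 and H2ac4 had log2 fold changes of 0.26, 0.22, 0.21 and 0.20 there, and a pair of peaks near H3f3b, which encodes the replacement histone H3.3, had 0.47 and 0.40. Larger gains lay at weak intergenic peaks, each called in 0 DMSO libraries. Those assigned to H2bc15, at 1.24 and 1.18, went from 51.6 to 121 and from 48.5 to 110 normalised reads in the authors' deposited table. Another, assigned to H4c12, went from 46.2 to 99.7 normalised reads there. The median over 61 gene-edge peaks of histone genes was 0.12, against -0.03 for gene-edge peaks of the same level deciles. Of the 61, 49 had a fold above 0. Counting the testis variants as well gave 14 higher and 0 lower of 131 peaks. A first, wider match of symbols had also taken in H13, which is not a histone gene and had 1 lower peak.

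A gene-edge peak of Mitf, the melanocyte regulator, rose by 0.27 in the authors' deposited table. A peak inside that gene, 68.3 kb from the nearest gene end, fell by 0.38 there. A peak assigned to Tubb3, a tubulin gene, rose by 0.60 with an adjusted p of 3.36e-23 in the authors' deposited table. The peak of highest level, on chromosome 17 from 39843027 to 39848758, had 96618 normalised reads in DMSO and 112534 under the inhibitor there. It was called higher, at 0.22 with an adjusted p of 9.43e-07 in the authors' deposited table. The peak next in level had 14563 normalised reads in DMSO, and the reason for the gap was not examined. At equal level and class, lower calls were scarcer on chromosome 7 than elsewhere, with an odds ratio of 0.74 and a 95% interval of 0.611 to 0.871 (adjusted p = 0.0172 over 20 chromosomes). The error came from 1000 resamples of 1 Mb blocks, chosen after a test at equal level alone, with peaks taken as independent, had also called chromosomes X, 2 and 13 (adjusted p of 0.00969, 0.0391 and 0.0391). In blocks these had odds ratios of 0.778, 1.19 and 1.16 and did not pass, at an adjusted p of 0.507, 0.161 and 0.507.

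The tests on signal over background, GC content, histone chance and shared histone reads, and the groups without gene-edge peaks, were chosen after the results were seen. A test of a tagmentation difference that moves all distal sites together was replaced by the one on GC content after its result was seen. It had predicted an SD of fold over standard error near 1 among strong distal peaks, and found 1.85. Changes that differ between sites also raise this SD, so the test cannot exclude a shared distal shift beside them.

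The surplus of lower over higher peaks was weighed first. After centring on the median of tested peaks 83.2% of changed peaks were still lower, which argues against an offset of that size as the whole cause. Taking -0.17 off every log2 fold would, however, even the split and leave gene edges at a median of 0.14. Weaker signal alike at all sites would touch gene edges as often as other peaks of equal level, and the odds ratio was 0.133. GC content could not be examined without sequence, so 14.5% lower calls among the strongest distal peaks, against 1.3% at gene edges of the same deciles, cannot be told apart from unequal recovery by GC. A tagmentation difference between the groups and an effect of the inhibitor itself both stay open, and neither was tested apart from these.

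Lower peaks lay near one another more often than chance placement gave. Of lower peaks, 34.5% had another within 25 kb, against a mean of 24.6% and a highest value of 26.9% in 1000 permutations within level and class. Copy loss in treated cells would lower gene-edge peaks nearby as well. Yet 514 such peaks had a median of -0.08 and a 25th percentile of -0.19, beside -0.66 for the grouped lower peaks. Of these 514 peaks 11.7% were called lower, but they include gene-edge peaks that are themselves members of the groups. With groups formed without gene-edge peaks, 400 gene-edge peaks nearby had a median of -0.06 and 1.5% were lower, against 1.55% of other gene-edge peaks, which argues against copy loss as the whole cause. Regional GC content was not examined, and an effect of the inhibitor stays open, untested.

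The histone genes had 14 higher peaks, against 0.592 on average in draws of peaks of the same level decile and class. The top decile spans log2 levels of 9.8 to 16.68 with a median of 1310 normalised reads, so matching was coarse there. The gene-edge peak of H2bc15, in that decile, had 3444 in DMSO, and stronger peaks were called at smaller folds. The group was also picked for its calls, so this count cannot set chance aside. A copy gain of the chromosome 13 histone loci would raise their other peaks too, but 22 peaks there not assigned to histone genes had a median of -0.15, against 0.14 for histone-gene peaks. Reads shared between near-identical histone genes remain open: peaks over 1 kb from a gene edge in these loci had a median of -0.09, the value of matched peaks, yet 3 of those 41 were higher and 2 lower, which decides nothing. An effect of the inhibitor also stays open, untested.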
